A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

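RNA was measured by sequencing in 4 libraries of the Hsf1 anchor-away strain, 1 library for each combination of temperature (30 °C, or 10 min at 39 °C) and rapamycin (none, or 1 µM for 45 min). Per the labels the input was total RNA, extracted with phenol and chloroform, and the libraries were made with the Illumina TruSeq chemistry; strand handling, read length and any removal of ribosomal RNA are not given in the sources used here. TopHat and HTSeq with the genome build sacCer3 are named in the submitters' processing notes, without versions or settings.

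The deposited signal values are gene read counts that were divided by 1 size factor per library and rounded to 2 decimals. This was read from the values: in every library 100% of the values above 0 were whole multiples of 1 step, within 0.0055. How the size factors were made is not given in the sources used here. Median-of-ratios factors recomputed from the recovered reads matched the deposited ones to within 0.514%. The step, the value of 1 read, was 1.43 at 30 °C without rapamycin, 0.888 at 30 °C with rapamycin, 1.5 in heat shock without and 0.961 in heat shock with rapamycin. Recovered reads summed to 1561620, 3231228, 2026880 and 2254007 in the same order. The 3-read floor used for features without reads was therefore 4.29, 2.67, 4.50 and 2.88.

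The table lists 7126 features. Of these, 6162 matched a gene of the RefSeq annotation of assembly R64, the assembly that sacCer3 names, by systematic name or, failing that, by gene symbol. The other 964 did not, 679 of them with systematic Y names. Names, biotypes and coordinates come from that table. All 28 mitochondrial Q features and all 14 ribosomal RNA features are listed at 0, and 766 features are at 0 in all 4 libraries, 229 of them protein-coding, so a gene listed at 0 was not necessarily free of reads. Genes with near-identical copies, overlapping frames and antisense frames are named as uncertain.

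The design fixed before the data were examined had 1 branch for counts and 1 for normalised values. The table holds normalised values, so the deposited values were used as they stand. Features with a mean of at least 5 over the 4 libraries were kept, 5642 in all, of which 5431 are protein-coding. Ratios of 2 libraries were taken on log2(value + 1), and the difference of heat shock ratios is the ratio with rapamycin minus the ratio without. A 2-fold difference, 1 on the log2 scale, is a fixed rule of size and not a test; 4-fold counts are given beside it. Folds are 2 to the power of the log2 ratio, and against a library without reads the bound uses the 3-read floor without the pseudocount. The 95% interval of a fold is the exact conditional binomial interval of the read ratio, without the pseudocount. Intervals of list medians come from 1000 Poisson draws of the reads, and intervals of shares are exact Clopper-Pearson intervals. All of them cover counting error only, and reads without molecular identifiers are not independent molecules. With 1 library per group no spread between cultures can be estimated, no library can be left out and no other split of the libraries exists.

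The same fixed plan held 21 gene lists, each described by its members at least 2-fold higher, at least 2-fold lower and between, and by the percentile of its median among 10000 random lists of the same size, drawn from 20 expression bins. Percentiles describe these libraries only. HSP32 of the Msn2/4-type list and ASP3-1 of the nitrogen catabolite list were listed at 0. The genes named are 30 fixed genes, the 8 highest and 8 lowest kept features of each comparison and of the difference, and up to 3 members per list and comparison with the largest change in the direction of the list median; exceptions are stated where they occur. A named gene was set apart for a closer look where the same contrast went at least 2-fold in opposite directions between arms, and a list where its medians did so by at least 1.2-fold each.

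The other settings fixed before the data were seen were median-of-ratios size factors, division by the library total, pseudocounts of 0.25 and 5, filters at a mean of 1, at a mean of 20 and none, protein-coding features alone, and a total without the 20 features of highest mean. Settings added after the data were seen were TMM scaling of the recovered reads, division by the protein-coding total and a count test. The count test is edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment on an additive model of heat and rapamycin. It leaves 1 residual degree of freedom, counts any interaction of heat and rapamycin as noise, and compares these libraries, not the conditions. Exonic A and T runs were measured in the RefSeq exons on the R64 sequence, and neighbouring genes were taken from their order in the same annotation.

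The code was tested on simulated data, Poisson counts for the real features and library sizes with 200 genes changed in heat shock without rapamycin. At least 2-fold were 42 of 50 genes changed by 2.5-fold, 49 of 50 at 4-fold, 50 of 50 at 8-fold and 49 of 49 kept genes at 16-fold. Of 5456 unchanged features, counting error alone put 90 past 2-fold in heat shock without rapamycin, 41 in heat shock with it, 60 for rapamycin at 30 °C, 57 for rapamycin in heat shock and 160 for the difference of ratios. Of 200 simulated lists of unchanged genes in heat shock without rapamycin, 10 fell outside the middle 95% of random lists. Such a share follows from the construction, because these genes were drawn at random with independent counts. It checks the code and does not show how far lists of co-regulated genes would stray. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.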

Results

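RNA was sequenced from 4 samples of 1 strain of the budding yeast Saccharomyces cerevisiae whose genotype label is Hsf1-AA, an anchor-away strain for Hsf1. Hsf1 is the transcription factor that activates chaperone genes in heat shock. The series asked what Hsf1 does at its target genes in heat shock, and RNA-seq measured the transcripts with and without the drug that withdraws it. In the anchor-away method, rapamycin tethers a tagged nuclear protein to an abundant protein that leaves the nucleus, so that the tagged protein is withdrawn from its target genes while its mRNA can remain. The samples formed a square of temperature and drug: 30 °C without rapamycin, 30 °C with 1 µM rapamycin for 45 min, 10 min of heat shock at 39 °C without rapamycin, and 10 min at 39 °C with rapamycin. Each group held 1 library, so no difference below has a replicate check and the ratios were not tested. Intervals in parentheses are 95% counting intervals of the reads alone and leave out the variation between cultures. The labels do not say whether rapamycin preceded the heat shock or whether the strain carried a rapamycin-resistant TORC1.

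The libraries held 1561620 assigned reads at 30 °C without rapamycin, 3231228 at 30 °C with rapamycin, 2026880 in heat shock without rapamycin and 2254007 in heat shock with rapamycin. Values below are the deposited normalised read counts, in which 1 read was worth 1.43, 0.888, 1.5 and 0.961 units in the same order. Protein-coding genes took 64.7%, 59.5%, 59.6% and 66.5% of the reads, each share with an exact binomial interval of at most 0.0750 points to either side. Transfer RNA took 14.3%, 18.3%, 13.8% and 10.1%, within 0.0549 points. Of the 7126 features listed, 5642 had a mean of at least 5 units and entered the comparisons.

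HSF1 itself (chromosome VII, 368753 to 371254 in the R64 assembly, a protein-coding gene) was at 157, 107, 288 and 225 normalised reads in the 4 libraries, in the order given above. It was 1.83-fold higher in heat shock without rapamycin (1.44 to 2.34) and 2.08-fold higher with it (1.67 to 2.63). Anchor-away moves the protein and leaves the gene intact, so these mRNA values do not check whether Hsf1 was depleted. The genes of the general stress factors read 126, 118, 199 and 210.4 for MSN2 and 194, 186, 179.9 and 271 for MSN4. Among the reference genes, ACT1 read 3820.1, 3607, 3736 and 2866, TAF10 read 154, 107, 81.0 and 73.0 and ALG9 read 142, 100.4, 162 and 121.

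The first comparison asked which transcripts differed after 10 min at 39 °C when no rapamycin was present. The medians of the fixed lists of Hsf1-target cytosolic chaperone, general stress and storage carbohydrate genes stood far above their 30 °C level, and that of ribosome biogenesis genes far below it. All 20 fixed Hsf1-target cytosolic chaperone and co-chaperone genes were at least 2-fold higher, with a median of 17.5-fold (log2 4.13, 3.90 to 4.32), above all 10000 random lists of the same size and expression. Together they took 0.868% of all reads at 30 °C (exact binomial interval 0.853% to 0.882%) and 8.88% in heat shock (8.84% to 8.92%). Of the 5642 features, 1115 were at least 2-fold higher and 1089 at least 2-fold lower, and 443 and 361 passed 4-fold. The higher features made up 50.6% of those past 2-fold, and 29.9% when each library was divided by its total, a scaling that shifts the median of all features by -0.44 on the log2 scale.

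SSA4, a heat-inducible cytosolic Hsp70 (YER103W, chromosome V, 364589 to 366517), was at 169 normalised reads at 30 °C and 42107 in heat shock, 248-fold higher (208 to 302). BTN2, a factor that sorts misfolded proteins (YGR142W, chromosome VII, 772454 to 773686), was 157-fold higher (127 to 201), and the small heat shock protein gene HSP42 74.6-fold higher (62.6 to 90.8). HSP82 (YPL240C, chromosome XVI, 96496 to 98625), an Hsp90 gene, went from 612 to 27356, and its constitutive paralog HSC82 from 4621 to 21984. HSP104, the disaggregase gene (chromosome XII, 88623 to 91349), had the highest heat shock value in the list, 54770 against 1473. The J-domain protein genes differed in their folds, with SIS1 at 23.3-fold and YDJ1 at 4.34-fold higher, and the Hsp90 co-chaperone STI1 was 17.2-fold higher. The coding sequences of SSA1 and SSA2, of SSA3 and SSA4 and of HSP82 and HSC82 are alike, so how reads were divided within each pair is uncertain. Summed, the pairs were 4.95-fold, 162-fold and 9.43-fold higher.

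Among the Msn2/4-type general stress genes, 36 of 38 were at least 2-fold higher and none at least 2-fold lower (median 4.08, above all 10000 random lists). SPI1, a cell surface protein gene, was 78.7-fold higher (50.4 to 144), TKL2, a transketolase gene, 66.3-fold (37.4 to 157) and PHM7 54.9-fold (38.3 to 86.5). The cytosolic catalase gene CTT1 was at 4942 against 124. All 5 genes ascribed to both Hsf1 and Msn2/4 were at least 2-fold higher (median 5.72, above all 10000 random lists), led by HSP26 at 258-fold (186 to 385), TMA10 at 255-fold (162 to 477) and HSP12 at 52.7-fold (43.4 to 65.7). Of 17 trehalose and glycogen genes, 15 were at least 2-fold higher (median 3.10, percentile 99.99). These included phosphoglucomutase PGM2 (40.9-fold), the trehalose synthase subunit gene TSL1 (26.8-fold), glycogen phosphorylase GPH1 (26.1-fold) and trehalose-phosphate synthase TPS1 (10-fold). Outside the lists, HSP30, a plasma membrane heat shock protein gene, had the highest ratio of all kept features, 316-fold (223 to 493). ATG41, an autophagy gene, was 179-fold higher (98.5 to 451), YNL194C 95.4-fold (48.6 to 291) and ROQ1 79.3-fold (33.0 to 476), the last from 3 reads at 30 °C.

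All 61 ribosome biogenesis genes were at least 2-fold lower in heat shock (median -2.95, -3.21 to -2.83, below all 10000 random lists). NSR1, a nucleolar protein gene, was at 18.0 against 1169.5, 61.6-fold lower (37.0 to 126), and BRX1 32.2-fold lower (14.3 to 139). RPA12, an RNA polymerase I subunit gene, was 30.1-fold lower (8.52 to 1996) and had 1 read in heat shock. Other ribosome assembly genes outside the list were among the lowest ratios. RPF2 was 87.3-fold lower (25.6 to 5762, 1 read in heat shock), REI1 62.4-fold (22.6 to 690.5, 2 reads) and ECM1 27.5-fold (11.1 to 164, 3 reads). FYV7 had no read in heat shock and was at least 5.40-fold lower, taking 3 reads as the floor per library. YOR309C, which matched no RefSeq gene, had the same bound, at least 5.40-fold. Of 138 cytosolic ribosomal protein genes, 102 were at least 2-fold lower and none at least 2-fold higher (median -1.32, below all 10000 random lists), with RPL22B at 15.0-fold and RPS9B at 8.79-fold lower. Reads of ribosomal protein paralogs are hard to divide, so single members are uncertain.

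Of 11 mitochondrial chaperone genes, 5 were at least 2-fold higher (median 0.85, percentile 96.8), the disaggregase gene HSP78 (49.9-fold), MDJ1 (10.5-fold), the chaperonin genes HSP10 (9.60-fold) and HSP60 (5.16-fold) and the Hsp70 gene SSC1 (log2 1.44). In the endoplasmic reticulum list 4 of 15 were at least 2-fold higher (median 0.69, percentile 97.6): the Hsp70 gene KAR2 (8.41-fold), the disulfide isomerase gene MPD1 (11-fold), the oxidase gene ERO1 (9.66-fold) and the exchange factor gene SIL1 (3.09-fold). Ribosome-associated chaperones had 3 of 7 genes at least 2-fold lower (median -0.93, percentile 7.74), the Hsp70 genes SSB1 (7.11-fold) and SSB2 (5.6-fold) and their J-domain partner ZUO1 (3.44-fold). The CCT chaperonin and prefoldin list had 7 of 14 at least 2-fold lower (median -1.0, percentile 0.690), with CCT7 3.18-fold lower. Proteasome subunits had a median of 0.43 (percentile 95.3, 5 of 32 at least 2-fold higher), which was -0.01 on library totals. The 5 were PRE2, PRE7, PRE10, RPN7 and RPN8, with log2 ratios of 1.03 to 1.25. SSC1, PRE7, PRE10 and, in the later comparisons, LHS1 and MOH1 lie outside the fixed rule for naming genes and were chosen after their values were seen. RPN4, the gene of the proteasome transcription factor, was 4.97-fold higher (4.20 to 5.96).

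G1 cyclin and S phase genes were lower, 11 of 18 by at least 2-fold (median -1.29, below all 10000 random lists), including the cyclin genes CLN2 (8.89-fold) and PCL1 (6.68-fold) and the ribonucleotide reductase gene RNR1 (6.63-fold). Amino acid biosynthesis genes of the Gcn4 type had a median of -0.64 (percentile 0.290, 15 of 42 at least 2-fold lower). Nitrogen catabolite and retrograde genes had a median of 0.64 (percentile 98.6, 12 of 28 at least 2-fold higher). The medians of glycolysis (0.52, percentile 60.8), cell wall integrity genes (0.52, percentile 89.3), ergosterol synthesis (-0.13, percentile 39.0) and core histones (-0.13, percentile 39.1) lay inside the middle 95% of random lists. Of the mating type lists, the MATalpha markers were abundant at 30 °C, with MF(ALPHA)1 at 1248 and SAG1 at 442, and had a median ratio of -1.03 (percentile 5.64). Only 3 of 6 MATa markers were kept, with STE2 at 22.9, STE6 at 57.2 and BAR1 at 4.29 normalised reads at 30 °C, with a median of 0.51 that was -0.00 without the filter on low values. Meiosis and sporulation genes, 15 of 22 kept and none above 78.8 in any library, had a median of 0.67 (percentile 87.3).

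The next comparison asked how heat shock and 30 °C differed when rapamycin was present. General stress, storage carbohydrate and ribosome biogenesis genes again stood far from their 30 °C level, whereas the Hsf1-target chaperone list as a whole did not. That list had a median log2 ratio of 0.06 (-0.11 to 0.25, percentile 92.8), with 5 of 20 members at least 2-fold higher, 3 at least 2-fold lower and 12 between. It took 0.287% of reads at 30 °C (0.281% to 0.293%) and 0.739% in heat shock (0.728% to 0.750%). Over all features 1034 were at least 2-fold higher and 825 at least 2-fold lower, and 356 and 205 passed 4-fold. The higher ones were 55.6% of those past 2-fold, and 78.6% on library totals, which shift the median of all features by 0.40. In this comparison the Hsf1-target median was 0.46 on library totals.

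The 5 chaperone genes that were at least 2-fold higher were HSP42 (8.59-fold, 7.54 to 9.91), HSP104 (6.99-fold, 6.58 to 7.44), CUR1 (5.19-fold, 2.98 to 11.4), SSA1 (2.41-fold, 2.13 to 2.75) and MBF1 (2.24-fold, 1.99 to 2.52). YDJ1 was 2.60-fold lower (2.17 to 3.16), BTN2 2.03-fold (1.59 to 2.63) and the Hsp70 exchange factor gene FES1 2.02-fold (1.57 to 2.65). SSA4 was at 402 in heat shock and 525 at 30 °C. HSP82 was 2.0-fold higher (1.78 to 2.24), just under the size rule. The summed pairs had folds of 1.59 for SSA1 and SSA2, 1.10 for HSP82 and HSC82, and 1.01 in the lower direction for SSA3 and SSA4.

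Of the Msn2/4-type genes, 35 of 38 were at least 2-fold higher (median 3.33, 3.20 to 3.42, above all 10000 random lists). CTT1 was 47.4-fold higher (40.2 to 57.5), PHM7 41.1-fold (31.8 to 56.6) and the phosphogluconate dehydrogenase gene GND2 39.5-fold (24.4 to 84.0). PAI3, a proteinase A inhibitor gene, had no read at 30 °C and was at least 15.9-fold higher. The highest ratio of any kept feature was that of HXT5, a hexose transporter gene, at 848 against 7.11 (105-fold, 60.3 to 277). FMP48 was 37.0-fold higher (27.3 to 55.1) and GAC1, a glycogen phosphatase regulator gene, 36.0-fold (25.3 to 58.4). All 5 genes ascribed to both factors were at least 2-fold higher (median 2.01, percentile 99.4), from UBI4 at 2.63-fold to HSP12 at 16.4-fold. In the trehalose and glycogen list 15 of 17 were at least 2-fold higher (median 2.69, above all 10000 random lists), with PGM2 at 24.8-fold, TSL1 at 16.5-fold and TPS2 at 13.9-fold.

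All 61 ribosome biogenesis genes were at least 2-fold lower (median -2.57, -2.66 to -2.39, below all 10000 random lists), with NSR1 46.4-fold (34.2 to 68.8), NOG1 15.8-fold and CBF5 13.7-fold lower. REI1 was 58.6-fold lower (28.4 to 271), ALB1 29.0-fold (16.8 to 71.2) and the cyclin gene PCL1 65.8-fold (23.5 to 5295, 1 read in heat shock). Ribosomal protein genes had 49 of 138 at least 2-fold lower (median -0.83, below all 10000 random lists). Also below 0 were the ribosome-associated chaperones (-1.02, percentile 1.58), the CCT and prefoldin list (-0.71, percentile 0.720), G1 cyclin and S phase genes (-0.93, percentile 0.0100), Gcn4-type genes (-0.56, percentile 0.130) and MATalpha markers (-1.16, percentile 1.83). Nitrogen catabolite and retrograde genes had a median of 0.54 (percentile 98.8), cell wall integrity genes 0.43 (percentile 95.7), meiosis genes 0.91 (percentile 91.0) and the 3 MATa markers 1.57 (percentile 95.5). The medians of the mitochondrial chaperones (0.03), endoplasmic reticulum chaperones (0.41), proteasome (0.04), histones (0.24), glycolysis (-0.17, but 0.24 on library totals) and ergosterol synthesis (-0.30, but 0.10) lay inside the middle 95% of random lists. In those lists HSP78 (7.53-fold) and MDJ1 (2.29-fold) were the 2 mitochondrial genes at least 2-fold higher, and MPD1, SIL1, JEM1 and LHS1 the 4 of the endoplasmic reticulum. YNL143C, YHR095W and YKR040C were also among the 8 lowest ratios, through their values at 30 °C with rapamycin, which the next comparison describes.

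The comparison at 30 °C asked how the libraries with and without rapamycin, the drug that withdraws tagged Hsf1, differed without heat. The constitutive cytosolic Hsp70 gene SSA2 stood 10.6-fold lower with rapamycin and the constitutive Hsp90 gene HSC82 4.61-fold lower. The Hsf1-target list had a median log2 ratio of -0.69 (-0.86 to -0.59, below all 10000 random lists), with 7 of 20 at least 2-fold lower, 1 at least 2-fold higher and 16 below 0. Its share of reads was 0.287% against 0.868% without rapamycin. Far fewer features passed 2-fold than in heat shock: 265 higher and 227 lower of 5642, with 39 and 38 past 4-fold. Higher features were 53.9% of those past 2-fold, and 16.1% on library totals, which shift the median of all features by -0.35.

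SSA2 (YLL024C, chromosome XII, 95566 to 97485), the main constitutive cytosolic Hsp70 gene, was at 374 against 3972, 10.6-fold lower (9.58 to 11.8). SSA1 was 5.16-fold lower (4.59 to 5.85), HSC82 4.61-fold (4.31 to 4.94), CUR1 3.89-fold (2.08 to 8.89), YDJ1 2.32-fold (2.05 to 2.62) and STI1 2.20-fold (1.93 to 2.51). The summed SSA1 and SSA2 pair was 8.12-fold lower and HSP82 with HSC82 3.67-fold lower. SSA4 was the only list member at least 2-fold higher, at 525 against 169, 3.10-fold higher (2.55 to 3.83). Other heat-inducible genes were also higher, TMA10 by 4.56-fold (2.75 to 8.71), HSP26 by 3.58-fold (2.49 to 5.46), HSP30 by 3.44-fold (2.31 to 5.48) and ATG41 by 3.08-fold (1.51 to 8.04). The list ascribed to both factors had a median of 0.78 (percentile 96.9). The Msn2/4-type list had a median of 0.14 (percentile 72.9; -0.22 on library totals), with 2 members at least 2-fold higher, MSC1 and LSP1, and 2 at least 2-fold lower, PAI3 and MOH1, which both had no read with rapamycin.

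The highest ratio at 30 °C was that of YNL143C (chromosome XIV, 356794 to 357186), whose exon holds an A or T run of 32 bases, at 99117 normalised reads with rapamycin and 1355 without, 73.1-fold higher (68.6 to 78.0). YHR095W (26.5-fold), YKR040C (26.5-fold) and YMR290W-A (23.6-fold) matched no RefSeq gene, and YLR296W, with a run of 14 bases, went from 1 read to 97 (35.9-fold, 10.6 to 2405). GAT4 and YPR195C had no read without rapamycin and were at least 2.90-fold and 2.69-fold higher. The transfer RNA gene tV(AAC)O had 1 read without rapamycin and 29 with it (11-fold, 2.99 to 736). Besides SSA2, the lowest ratios belonged to low-count features. YLR456W had no read with rapamycin and was at least 5.90-fold lower, and YBR099C, YJR027W and YNL184C at least 3.76-fold, 3.76-fold and 3.22-fold lower. YER138W-A was 19.4-fold lower (6.59 to 1652), VLD1 10.4-fold (3.14 to 889) and FYV5 9.61-fold (2.86 to 826), each with 1 read with rapamycin. Overlapping and antisense frames among them cannot be told apart, because no strand information was given.

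Most other lists were close to 0 at 30 °C. Ribosomal protein genes had a median of 0.26 (percentile 99.9; 10 of 138 at least 2-fold higher) and ribosome biogenesis genes 0.22 (percentile 99.7), but -0.10 and -0.14 on library totals. RPS6A was 3.67-fold higher and the stalk protein gene RPP2A 3.35-fold. Nitrogen catabolite and retrograde genes, which rapamycin raises where TORC1 is sensitive, had a median of 0.17 (percentile 90.8, -0.19 on library totals). In that list 3 of 28 were at least 2-fold higher, the arginase gene CAR1 (2.64-fold), DAL3 (2.35-fold) and UGA4 (2.20-fold). The CCT and prefoldin list (-0.31, percentile 0.830) and the G1 cyclin and S phase genes (-0.33, percentile 1.60) were lower than most random lists, with CLB6 2.19-fold and CLN3 2.04-fold lower. Mitochondrial chaperones had a median of -0.20 (percentile 7.25), cell wall integrity genes -0.14, proteasome subunits -0.07, histones -0.07 and MATa markers -0.53. The medians of trehalose and glycogen genes (0.33), glycolysis (0.32), ribosome-associated chaperones (0.30), MATalpha markers (0.17), ergosterol synthesis (0.11), endoplasmic reticulum chaperones (0.07), Gcn4-type genes (0.01) and meiosis genes (0.01) were all below 0 on library totals, between -0.35 and -0.03.

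The comparison in heat shock asked how the libraries with and without rapamycin differed at 39 °C. All 20 Hsf1-target chaperone genes were at least 2-fold lower with rapamycin, by a median of 26.6-fold (log2 -4.73, -4.81 to -4.55, below all 10000 random lists). They took 0.739% of reads with rapamycin and 8.88% without. General stress genes lay close to their level without rapamycin, and ribosomal protein and ribosome biogenesis genes stood above it. Of 5642 features, 257 were at least 2-fold higher and 139 at least 2-fold lower, and 18 and 58 passed 4-fold. Higher features were 64.9% of those past 2-fold, and 92% on library totals, which shift the median of all features by 0.48.

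BTN2 was at 89.3 against 17462, 193-fold lower (159 to 242), and SSA4 105-fold lower (95.2 to 116). FES1 was 70.3-fold lower (57.5 to 89.0), STI1 37.1-fold (33.6 to 41.4), SSA2 36.7-fold (33.0 to 41.1), HSP82 32.3-fold (30.2 to 34.6) and SIS1 27.1-fold (24.5 to 30.2). The smallest ratios in the list were those of HSP42, 6.88-fold lower (6.55 to 7.24), and HSP104, 7.49-fold lower (7.31 to 7.68). Summed pairs were 25.4-fold (SSA1 and SSA2), 69.4-fold (SSA3 and SSA4) and 31.3-fold lower (HSP82 and HSC82). Genes outside the list had ratios of the same size. ZPR1, a folding factor gene for elongation factor 1A (YGR211W, chromosome VII, 915241 to 916701), was 88.5-fold lower (71.1 to 115), ATG41 51.4-fold (39.0 to 72.8) and LST8, a TORC1 and TORC2 subunit gene that lies 501 bp from SIS1 in the divergent direction (YNL006W, chromosome XIV, 620067 to 620978), 48.4-fold (39.1 to 62.3).

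Of the genes ascribed to both factors, 4 of 5 were at least 2-fold lower (median -2.49, percentile 0.225), with TMA10 at 16.4-fold and HSP12 at 1.86-fold lower. In the mitochondrial list 5 of 11 were at least 2-fold lower, MDJ1 (11.9-fold), HSP78 (9.37-fold), HSP10 (7.82-fold), HSP60 (7.77-fold) and SSC1 (log2 -2.11), while the list median was -0.36 (percentile 1.21; 0.12 on library totals). In the endoplasmic reticulum list the 2 genes at least 2-fold lower were ERO1 (6.80-fold) and KAR2 (5.14-fold), with a list median of -0.14 (percentile 6.93; 0.35 on library totals). All 32 proteasome genes were below 0 (median -0.48, -0.53 to -0.43, below all 10000 random lists), none by 2-fold, and the median was 0.01 on library totals. RPN4 was 4.35-fold lower (3.79 to 5.04). The Msn2/4-type list had a median of -0.27 (percentile 0.0200; 0.22 on library totals), with 2 of 38 at least 2-fold lower, SPI1 (4.76-fold) and the aldose reductase gene GRE3 (4.37-fold). Trehalose and glycogen genes had a median of -0.11 (0.37 on library totals), with no member past 2-fold.

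Ribosomal protein genes were higher with rapamycin in heat shock, 45 of 138 by at least 2-fold and 135 above 0 (median 0.83, 0.79 to 0.87, above all 10000 random lists). Ribosome biogenesis genes followed, 19 of 61 by at least 2-fold (median 0.75, above all 10000 random lists), with BRX1 4.26-fold (1.69 to 18.8) and RLP24 3.06-fold (1.26 to 11.1) higher. RPF2 had 1 read without rapamycin and 29 with it (11.5-fold, 3.08 to 759). Both medians were larger on library totals (1.31 and 1.22). The highest ratio was that of RRT15, at 90 reads against 1 (35.0-fold, 10.1 to 2303). YIL100W, YJR146W, MAL32, PUL3 and FYV7 had no read without rapamycin and were at least 2.35-fold, 1.28-fold, 1.07-fold, 1.07-fold and 1.5-fold higher, and SNO1 had 1 read against 15 (6.16-fold, 1.48 to 405). Gcn4-type genes (0.20, percentile 98.0) and ergosterol synthesis (0.28, percentile 98.7) were higher than most random lists. The remaining medians were 0.45 for ribosome-associated chaperones, 0.06 for CCT and prefoldin, 0.09 for G1 and S phase genes, 0.03 for nitrogen catabolite genes, 0.09 for cell wall integrity genes, 0.17 for histones, -0.42 for glycolysis (0.07 on library totals), 0.41 and 0.40 for MATa and MATalpha markers and 0.23 for meiosis genes.

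**Figure D1:**
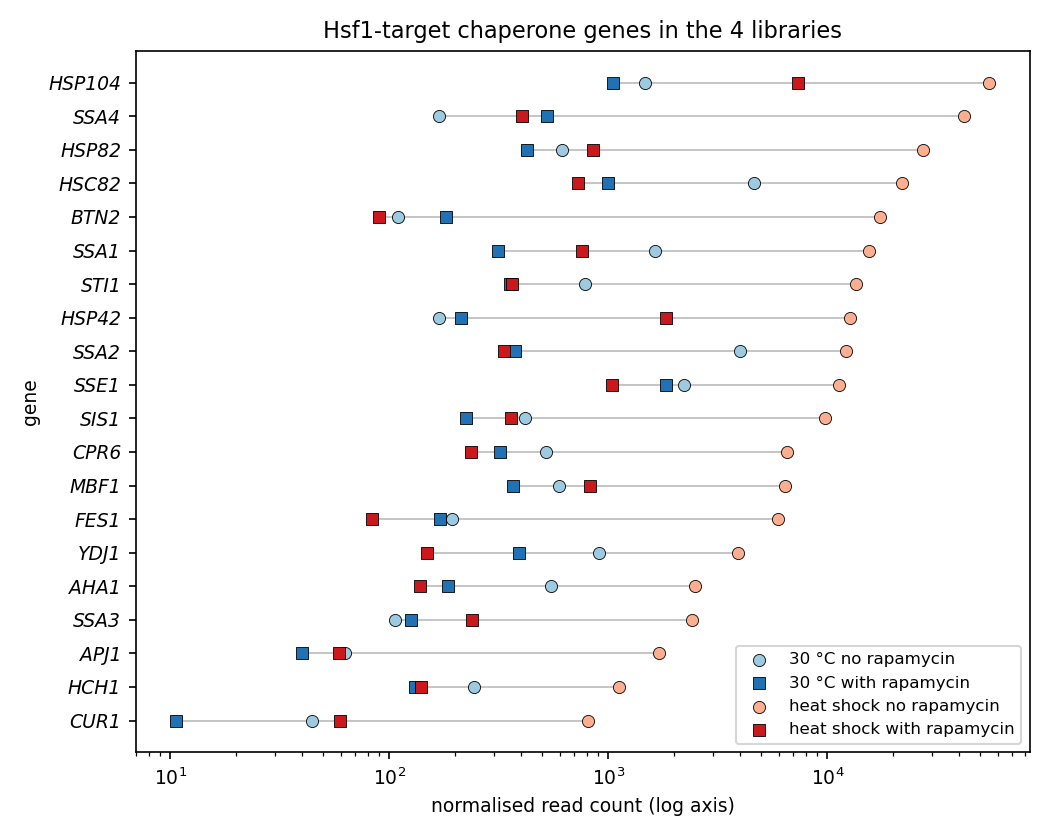
Normalised read count (log axis) of the 20 Hsf1-target chaperone genes, 1 line per gene and 1 point per library, with circles without and squares with rapamycin, in blue at 30 °C and in red in heat shock. In every gene the point for heat shock without rapamycin is the highest, up to 54770 for HSP104, and SSA2 reads 374 at 30 °C with rapamycin against 3972 without.

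The square of temperature and drug also allows the heat shock ratio to be compared between the libraries with and without rapamycin. All 20 Hsf1-target chaperone genes had a heat shock ratio at least 2-fold smaller with rapamycin, by a median of 10.1-fold (log2 -3.34, -3.50 to -3.16, below all 10000 random lists). In the Msn2/4-type list 8 of 38 were at least 2-fold smaller (median -0.49, percentile 0.0200; 0.35 on library totals). Across all 5642 features 468 had a ratio at least 2-fold smaller and 522 at least 2-fold larger, and 100 and 75 passed 4-fold. The larger ones were 52.7% of those past 2-fold, and 95% on library totals, which shift the median of all features by 0.84. These differences combine 4 libraries, none replicated, and were not tested.

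The ratio of SSA4 was 324-fold smaller with rapamycin (log2 -8.34), that of BTN2 319-fold (log2 -8.32), ATG41 158-fold, TMA10 74.6-fold, ZPR1 70.1-fold, FES1 61.9-fold and LST8 52.2-fold. The differences of SSA4, ATG41 and TMA10 include their higher values with rapamycin at 30 °C (log2 1.63, 1.62 and 2.19). In heat shock alone their rapamycin ratios were -6.71, -5.68 and -4.03. The ratios of the summed pairs were 164-fold (SSA3 and SSA4), 8.53-fold (HSP82 and HSC82) and 3.12-fold smaller (SSA1 and SSA2). The smallest differences in the chaperone list were those of CUR1 (3.43-fold) and SSA2 (3.46-fold), which were already lower with rapamycin at 30 °C. Of the genes at least 4-fold higher in heat shock without rapamycin, 69 had a ratio at least 4-fold smaller with it, where both measures share the libraries without rapamycin. They included 17 of the Hsf1-target list, 4 ascribed to both factors, 4 mitochondrial chaperone genes (HSP10, HSP78, HSP60 and MDJ1), 2 of the endoplasmic reticulum list (ERO1 and KAR2), 1 of the Msn2/4-type list (SPI1) and 40 in no list. Some in no list, such as GAT4 and GAL2, met this rule through higher values with rapamycin at 30 °C (log2 3.75 and 3.30). In heat shock their rapamycin ratios were 1.12 and -0.37. The 8 largest increases in the ratio were those of YHR175W-A, YLR456W, FYV5, YEL074W, RRT15, YIL100W, VLD1 and YLR162W. Each of these had 11 or fewer reads in at least 1 library of the heat shock ratios, so their differences depend on the pseudocount and no fold is given.

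Ribosomal protein genes (median 0.59, above all 10000 random lists, 36 of 138 at least 2-fold larger) and ribosome biogenesis genes (0.58, above all 10000 random lists, 14 of 61) had larger, meaning less negative, log2 heat shock ratios with rapamycin. The list ascribed to both factors had a median of -2.36 (percentile 0.440) and proteasome subunits -0.31 (percentile 0.110; 0.54 on library totals). Gcn4-type genes had 0.26 (percentile 98.0), CCT and prefoldin 0.29 (percentile 90.2) and MATa markers 1.06 (percentile 94.2). Medians below 0 that turned positive on library totals were those of glycolysis (-0.78, then 0.07), mitochondrial chaperones (-0.38, then 0.45), endoplasmic reticulum chaperones (-0.24, then 0.60), nitrogen catabolite genes (-0.20, then 0.65) and trehalose and glycogen genes (-0.18, then 0.67). Relative to the median of all features they hardly moved. Glycolysis stood at -0.84 and then -0.83, mitochondrial chaperones at -0.44 and -0.45, endoplasmic reticulum chaperones at -0.30 and -0.30, nitrogen catabolite genes at -0.26 and -0.25 and trehalose and glycogen genes at -0.24 and -0.23. Those of ribosome-associated chaperones (0.11), cell wall integrity genes (0.21), ergosterol synthesis (0.05), histones (0.13), G1 and S phase genes (0.17), MATalpha markers (0.33) and meiosis genes (0.24) were above 0 and inside the middle 95% of random lists.

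Across all 5642 features, the chaperone genes included, Pearson's r of the heat shock ratios without and with rapamycin was 0.802 and Spearman's rho 0.779, a description across genes, which are not independent replicates; the pair of ratios shares no library. Of the features at least 2-fold higher, 723 were shared by both arms, where independent lists of 1115 and 1034 would share 204, and 621 lower features were shared where 159 would be. Of the 443 features at least 4-fold higher without rapamycin, 377 were at least 2-fold higher with it and 66 were not. The rapamycin ratios at 30 °C and in heat shock had an r of 0.0824 across the same features.

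**Figure D2:**
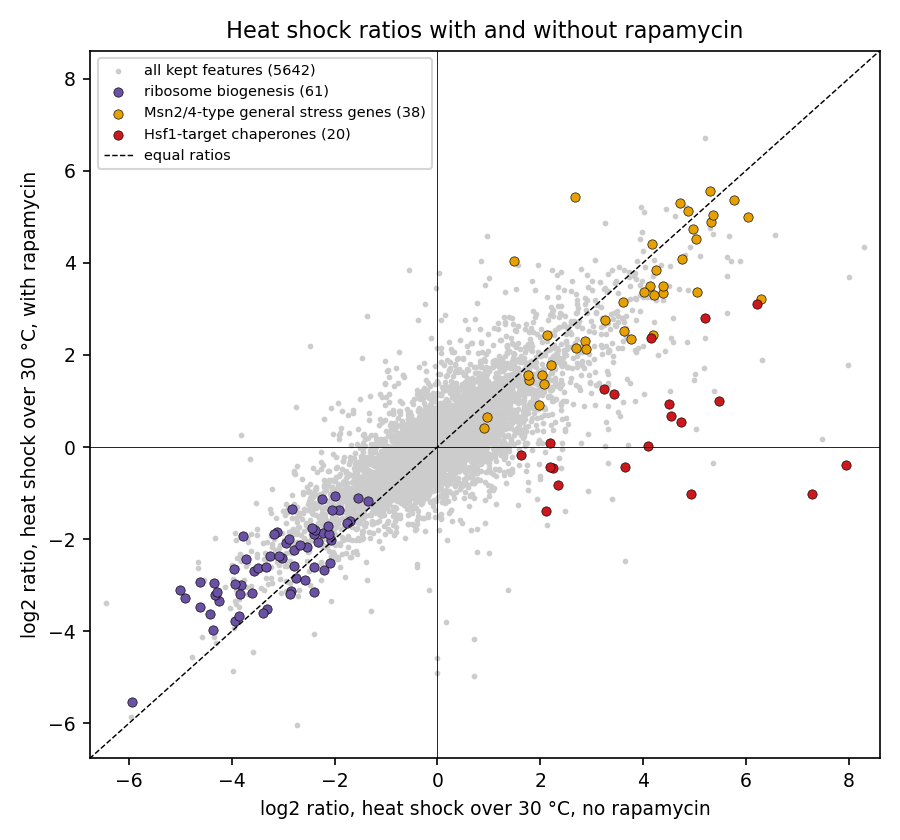
Log2 ratio of heat shock over 30 °C with rapamycin (vertical axis) against that without (horizontal axis) for the 5642 kept features (grey), with 3 fixed lists in colour and a dashed line of equal ratios. The medians of the Msn2/4-type genes (4.08 and 3.33) and of the ribosome biogenesis genes (-2.95 and -2.57) lie near the line, and the 20 Hsf1-target genes all lie below it, with medians of 4.13 without and 0.06 with rapamycin.

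**Figure D3:**
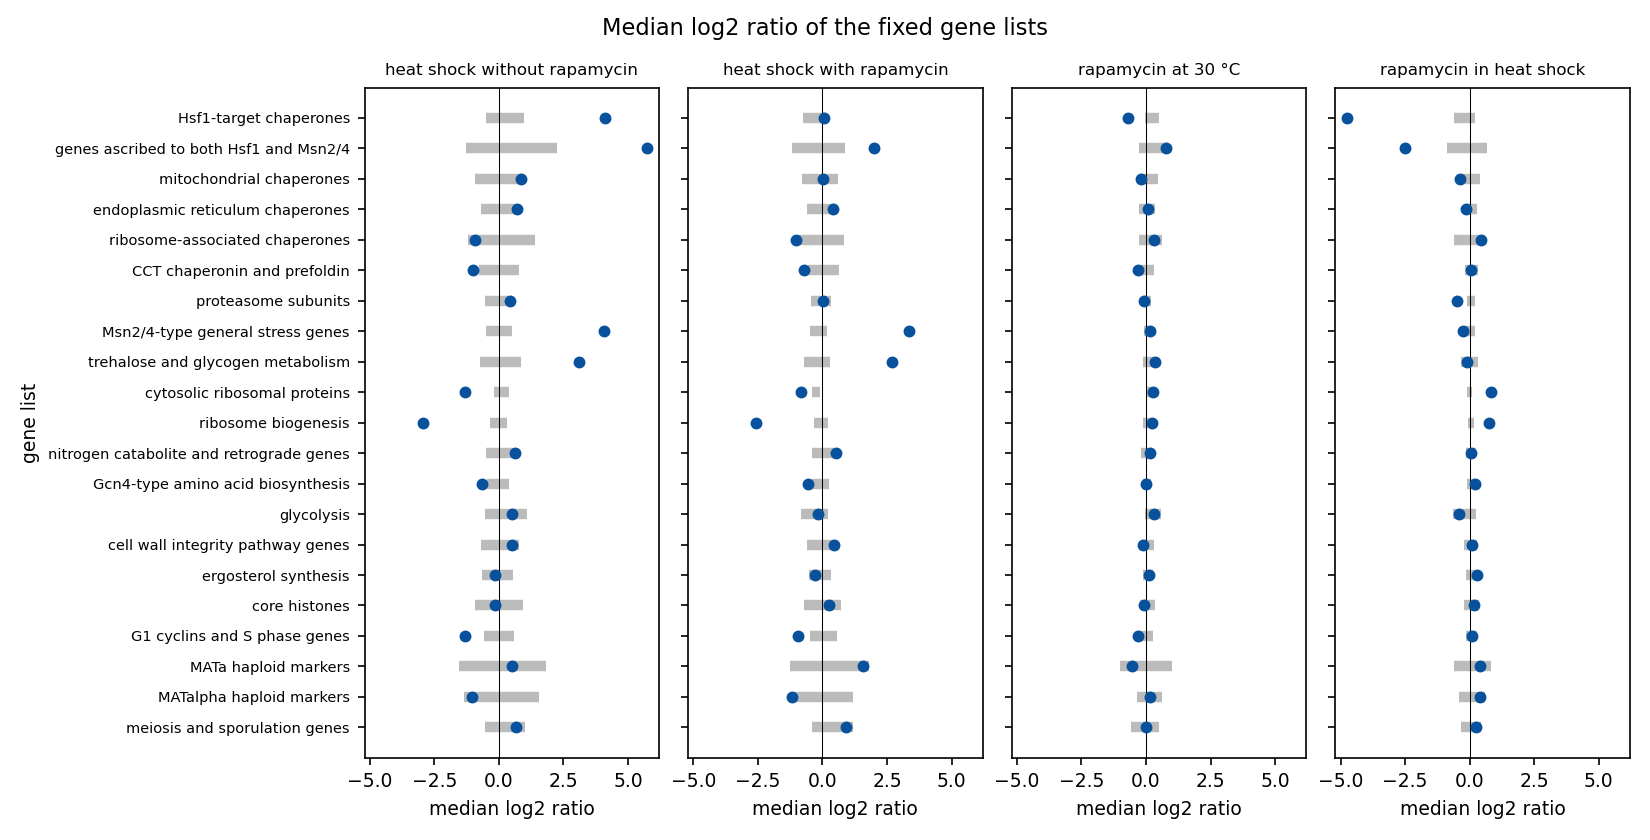
Median log2 ratio (points) of the 21 fixed gene lists in the 4 comparisons, with grey bars for the middle 95% of the medians of 10000 random lists matched on size and expression. The Hsf1-target list is outside the bar in 3 panels and inside it in heat shock with rapamycin (0.06), and division by library totals would move the points and bars of a panel by about -0.44, 0.40, -0.35 and 0.48 from left to right.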

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

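All tests in this part were chosen after the results were seen, and the first form of the test on carried-over reads was replaced after its value was known, as was a test on the Msn2/4-type list median (0.14, against a bound of 1), which was merged into it. The results below went one way in one arm and the opposite way in the other, by at least 2-fold each for a gene and at least 1.2-fold each for a list median. Of 223 named genes 16 did so, 1 of them (YHR175W-A) in both contrasts, and of 21 lists 3. None of these differences was tested, because each arm holds 1 library per condition. Values are log2 ratios.

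With heat shock, the opposite directions without and with rapamycin were as follows. BTN2 had 7.30 and -1.02, difference -8.32, and FES1 4.94 and -1.01, difference -5.95. ZPR1 had 3.65 and -2.48, difference -6.13, and YDJ1 2.12 and -1.38, difference -3.50. SPS4, a sporulation gene with 7, 8, 3 and 17 reads in the 4 libraries, had -1.0 and 1.09, difference 2.10. FYV5, with 12, 1, 4 and 13 reads, had -1.38 and 2.83, difference 4.21. YHR175W-A, with 9, 1, 1 and 8 reads, had -2.47 and 2.20, difference 4.67, and it also went opposite ways with rapamycin, -2.88 at 30 °C and 1.80 in heat shock, which is the same difference of 4.67.

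With rapamycin, the opposite directions at 30 °C and in heat shock were as follows. SSA4 had 1.63 and -6.71, difference -8.34, ATG41 1.62 and -5.68, difference -7.31 and TMA10 2.19 and -4.03, difference -6.22. HSP26 had 1.84 and -2.49, difference -4.32, HSP30 1.78 and -2.19, difference -3.97 and ROQ1 1.52 and -2.89, difference -4.41. CLN3, a G1 cyclin gene, had -1.03 and 1.44, difference 2.48. YLR162W had -1.23 and 2.24, difference 3.47, and YEL074W, with 24, 7, 1 and 8 reads, had -2.29 and 1.80, difference 4.09. Among list medians, the genes ascribed to both Hsf1 and Msn2/4 had 0.78 and -2.49, difference -3.27. Glycolysis had 0.32 and -0.42, difference -0.74, which became -0.05 and 0.07 on library totals. The MATa markers had -0.53 and 0.41, difference 0.94, over 3 genes.

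SSA4, HSP26, TMA10, HSP30 and ATG41 were 3.08- to 4.56-fold higher at 30 °C with rapamycin, and all 5 are among the 8 highest heat shock ratios without rapamycin. Rapamycin acting through TORC1 would lower ribosome biogenesis genes, but their median was 0.22 (0.16 to 0.28), above the bound of -0.2 set for it, and -0.14 on library totals, where it is also above that bound. It would raise nitrogen catabolite and retrograde genes. Their median was 0.17 (percentile 90.8, and -0.19 on library totals), with 3 of 28 at least 2-fold higher and 21 above 0, and no bound was set for them. A small share of the heat shock profile in this library, from carried-over reads or slight heating, could raise heat-inducible genes by a like percent of their heat shock value, 0.769% to 1.39% in these 5. HSP12 gained 1.37%, inside that range. BTN2 gained 0.412%, PHM7 0.389%, HSP42 0.351%, DDR2 0.268%, ALD3 0.0547%, CTT1 -0.216% and FMP45 -0.591%. Of 20 strongly heat-induced Msn2/4-type genes 6 were below 0 and 7 at or above the lowest of the 5. The median gain of the 20 was 0.376 of that of SSA4 (-0.03 to 1.00), an interval too wide to decide, and -0.71 on library totals. The first form, the summed gain divided by that predicted from SSA4, was 3.08 (2.49 to 3.74), with 76.9% of the sum from 3 of 38 genes. It met its bound of 0.7, but that bound had no upper limit. The summed gain was larger than a share like that of SSA4 predicts and came mostly from 3 genes, so the first form does not decide on this explanation. A small share of the heat shock profile cannot be told apart from the other explanations. A rise from the removal of Hsf1 itself remains open and was not tested.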

How the results depend on the processing

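The edgeR test, the TMM scaling and the protein-coding total were added after the data were seen; all other alternatives were fixed before the data were examined. No ratio of the 223 named genes and no list median of at least 2-fold changed sign under the 9 alternatives that recomputed them (975 of 1115 gene ratios under the filter at a mean of 20). Protein-coding features alone and the total without the 20 highest features were run for gene counts alone. Of 110 recomputed gene counts 82 stayed within 1.5 times the reported count, and 23 of the 28 others came from scaling to a total. Of 945 list medians 759 and of 9895 named gene ratios 8602 stayed within their counting intervals. These totals are partly built in: a filter cannot change the ratio of a single gene, and median-of-ratios factors nearly repeat the deposited ones. Under division by the library total 417 of 1115 gene ratios stayed, and 579 under the protein-coding total. Of the list medians, 7 stayed and 98 moved under the library total, and 19 stayed and 86 moved under the protein-coding total. All 10 counts stayed within 1.5 times under TMM, median-of-ratios factors, a pseudocount of 0.25, a filter at a mean of 20 and protein-coding features alone. Of 67 list medians of at least 1.2-fold, 15 changed sign under at least 1 of the 9.

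Division by the library total gave 724 higher and 1701 lower features in heat shock without rapamycin, 1590 and 433 with rapamycin, 113 and 591 for rapamycin at 30 °C, 874 and 76 for rapamycin in heat shock, and 2482 larger and 131 smaller ratios. The Hsf1-target medians were then 3.69, 0.46, -1.05, -4.25 and -2.48 for the difference. The total without the 20 highest features gave 158 and 374 for rapamycin at 30 °C, 681 and 86 in heat shock, and 1638 larger and 176 smaller ratios. The protein-coding total gave 549 lower features in heat shock with rapamycin, 139 and 423 for rapamycin at 30 °C, 586 and 91 in heat shock, and 1587 larger and 181 smaller ratios, with Hsf1-target medians of 3.81, 0.30, -0.93, -4.40 and -2.76. These shifts follow from the construction of the scalings, which move every ratio of a comparison together. With rapamycin at 30 °C a pseudocount of 5 gave 149 lower features, a filter at a mean of 1 gave 348 and no filter 408. With rapamycin in heat shock these 2 filters gave 220 and 293 lower features, and the correlation of the heat shock ratios was 0.749 and 0.729; the cause was not tested.

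The edgeR quasi-likelihood test called 1140 features higher and 1090 lower with heat, and 6 higher and 20 lower with rapamycin, of 5642 at a Benjamini-Hochberg adjusted p of 0.05 (2680 and 369 at an unadjusted p of 0.05). Depth limits features near the floor of 3 reads, 2.67 to 4.50 normalised reads by library.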

Other observations

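All tests in this part were chosen after the results were seen, and the tests on homopolymer tracts and on neighbouring genes replaced first forms whose values were known, while the test of a rapamycin effect was narrowed to one of the same size at both temperatures. Genes named here outside the fixed rule were chosen after their values were seen. Of the 69 genes that were at least 4-fold higher in heat shock without rapamycin and had a heat shock ratio at least 4-fold smaller with it, 40 were in none of the fixed lists. Of these 40, 21 had 3 or fewer reads at 30 °C without rapamycin, ROQ1 and SIP4 among them, and 20 had a mean under 50 normalised reads. Some of the 40 met the rule through a higher value with rapamycin at 30 °C, not a much lower one in heat shock. Their log2 rapamycin ratios at 30 °C and in heat shock were 3.75 and 1.12 for GAT4, 3.30 and -0.37 for GAL2 and 3.10 and -0.77 for COS5. Others were far lower in heat shock, such as ZPR1 (-0.34 and -6.47) and LST8 (0.11 and -5.60). ATG41 was at 11.4, 37.3, 2225 and 42.3 normalised reads at 30 °C without and with rapamycin and in heat shock without and with it. ZPR1 read 486, 385, 6128 and 68.2 in the same order, and LST8 87.2, 94.2, 3625 and 74.0. ROQ1, a regulator of a ubiquitin ligase in stress, read 4.29, 14.2, 418 and 55.7. SIP4, a transcription activator of gluconeogenic genes, read 2.86, 7.11, 124 and 9.61. PIN3 read 37.2, 56.0, 1209.9 and 156 and OPI10 28.6, 41.8, 955 and 128. The plasma membrane protein gene HSP30 read 38.6, 135, 12532 and 2753, so that its heat shock ratio was smaller with rapamycin but still 20.2-fold.

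In the other direction, 38 features were at least 4-fold higher in heat shock with rapamycin and under 2-fold higher without. None was in a fixed list, and 32 had a mean under 50 normalised reads. Of the 66 features at least 4-fold higher without and under 2-fold higher with rapamycin, 47 were in no fixed list and 22 had such a mean. Some of the 38 qualified through a low value at 30 °C with rapamycin. Log2 rapamycin ratios at 30 °C and in heat shock were -3.37 and 0.23 for VLD1 and -4.28 and -0.92 for YER138W-A. Others were higher with rapamycin in heat shock, such as RRT15 (1.38 and 5.13) and STP4 (-0.20 and 1.27). GAT4 of the 66 had 3.75 and 1.12. The 3 features of highest mean among the 38 were STP4 at 61.5, 53.3, 93.0 and 225, YDR133C, an unmatched frame, at 94.4, 20.4, 179.9 and 244, and YCX1 at 107, 37.3, 112 and 158. Among noncoding classes, the 76 kept small nucleolar RNAs had medians of 0.92, 0.09, 0.06 and -0.73 in heat shock without and with rapamycin and with rapamycin at 30 °C and in heat shock. The 29 kept transfer RNA features had 0.44, -0.98, 0.46 and -0.87, and the 5 small nuclear RNAs 0.65, -0.31, 0.70 and -0.66. On library totals, which shift the median of all features by -0.44, 0.40, -0.35 and 0.48, the same medians were 0.48, 0.50, -0.30 and -0.24 for small nucleolar RNAs, -0.01, -0.57, 0.11 and -0.38 for transfer RNAs and 0.20, 0.09, 0.34 and -0.17 for small nuclear RNAs. Under both scalings all 3 classes were lower with rapamycin in heat shock, small nucleolar and small nuclear RNAs were higher in heat shock without rapamycin, and transfer RNAs were lower in heat shock with it. Small nucleolar RNAs were also higher in heat shock with rapamycin, and transfer and small nuclear RNAs higher with rapamycin at 30 °C, under both. Signs flipped for small nucleolar RNAs with rapamycin at 30 °C, for small nuclear RNAs in heat shock with rapamycin and for transfer RNAs in heat shock without it. Their shares of reads in the 4 libraries were 9.93, 8.93, 13.6 and 11.6% for small nucleolar RNA, 14.3, 18.3, 13.8 and 10.1% for transfer RNA and 1.88, 2.34, 2.23 and 2.04% for small nuclear RNA.

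At 30 °C with rapamycin, 14 features had at least 80 normalised reads and were at least 4-fold higher than without, led by YNL143C at 99117 against 1355. In heat shock the highest log2 ratio of the 14 was 0.58, below their lowest at 30 °C, 2.14 (1.07 and 1.79 on library totals). The 14 were chosen for being at least 4-fold higher at 30 °C, so the selection set how low that side could go and favours such a gap. The comparison therefore cannot decide on an effect of rapamycin or of Hsf1 removal of the same size at both temperatures. An effect at 30 °C alone, or a smaller one in heat shock (median 0.05, or 0.54 on library totals), stays open too. Of the 8 whose exons were searched, YNL143C, MTC7, YIR018C-A and YLR296W hold an A or T run of 32, 25, 19 and 14 bases, against 12 of all 5527 searched genes (0.217%), and the 8 other genes with a run of at least 13 had a median of 0.89 (0.22 to 1.34, percentile 99.2, or 0.55 on library totals, against 0.01 for genes without a run). Reads from such tracts may explain these 4 members, but this cannot be told apart from other causes: TLC1 and TFC1, the best counted of the 8, had -0.14 and 0.00, the 4 past 2-fold (RUF21, YSW1, YMR030W-A and YOR034C-A) were at 1.43 to 7.15 normalised reads without rapamycin, YMR030W-A and YOR034C-A were also higher with it in heat shock (1.12 and 1.19), and the first form of the test, with the 4 members in it, gave 1.12 against a bound of 1 that was lowered to 0.5 after it was seen. The longest run in the 4 searched members without a tract (YLR297W, HPA2, TMA10 and MRPL39) was 6, so tracts inside their annotated exons do not account for those. Sequence outside the exons was not searched, and 6 features, YHR095W, YKR040C, YMR290W-A and 3 transfer RNAs, could not be searched.

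LST8 is divergent from SIS1, 501 bp apart, and YAR1, an ankyrin repeat protein gene, is divergent from HSP82, 858 bp apart, and both had heat shock ratios far smaller with rapamycin, with log2 differences of -5.71 and -4.52. A shared divergent promoter may account for the pattern, but this cannot be told apart from other causes. The other 3 divergent neighbours, MTQ1, EFB1 and BUD7, had -1.63, -1.29 and -0.72, a median of -1.29 (percentile 1.21). On library totals, which shift the median of all features by 0.84, it is -0.44 and misses the bound of -0.5. EFB1, whose value is that median, was not higher in heat shock without rapamycin (log2 -0.39) and was lower with it (-1.68), so it had no rise to lose. MTQ1 and BUD7 were higher in heat shock without rapamycin (1.59 and 1.45) and had -0.04 and 0.73 with it. Reads or transcripts running over from the chaperone gene into genes on its 5′ side were looked for in the 15 neighbours upstream in tandem. Their median difference was 0.45 (1.29 on library totals), with members from -1.36 (SYH1) to 1.64 (VPS62). In heat shock without rapamycin their median ratio was -0.51, with 1 of 15 at least 2-fold higher. With rapamycin in heat shock 0 of 15 were at least 2-fold lower. The rule set against run-over asked that no member be at -0.5 or less, so SYH1 left that test undecided. SYH1 itself was not higher in heat shock without rapamycin (log2 -0.44). As a set the 15 show no rise in heat shock that was lost with rapamycin, which argues against run-over in them. They do not cover LST8 and YAR1, which lie in the divergent direction and where run-over stays open. The first form of the promoter test took in LST8 and YAR1, with a median of -1.63 over 5 genes, both bounds were -1 before they were set to -0.5, and a test on 16 neighbours on the 3′ side (median 0.12) was dropped because it does not reach the 5′ side. With 3 genes and 1 library per group the shared promoter stays a hypothesis, and Hsf1 sites of their own were not analysed here.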
